A study of Arabidopsis thaliana with 4 samples.

How the data were processed

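The series holds droplet single-cell RNA libraries from 4 groups of Arabidopsis thaliana Col-0 seedlings, with 1 library per group. Per the labels' protocols, seedlings were grown on plates without sucrose, the whole aerial tissue of 5-day-old plants was digested into protoplasts, and protoplasts were sorted by GFP. The labels name the source as cotyledon. The untreated library (TMMpro:TMM-GFP line) was made with V2 chemistry, and the DMSO, BL and BIK libraries (TMMpro:GFP line, 2 h in 0.1% DMSO, 1 µM brassinolide or 50 µM bikinin) with V3 chemistry, per the labels' protocols.

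Per the submitters' processing notes, the authors used Cell Ranger, version not given in the sources used here, and the genome build TAIR10. The deposited matrices hold raw UMI counts per gene and cell barcode, as whole numbers with no normalization. All 4 share a list of 68875 features, of which 37686 are gene loci and 31189 are transposable element loci. The list has no reporter sequence, so GFP itself was not counted. Gene symbols came from a table of the TAIR10.1 annotation, which held 99.2% of the gene loci. The deposited barcodes numbered 13796 in the fusion library, 9217 in DMSO, 8384 in BL and 8198 in BIK, with 74859627, 81881183, 86853089 and 70852674 UMIs.

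The design, gene lists, markers, filters and all alternatives but those named below as added were fixed before the data were examined. Cells were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes, which left out 75, 1064, 572 and 912 barcodes for few genes and 0, 11, 38 and 19 for mitochondrial UMIs, in the order fusion, DMSO, BL, BIK. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its own threshold marked under 0.5% of cells in every library, so the top-scoring cells were removed at 0.8% per 1000 cells. This took out 1506, 532, 488 and 424 cells (11.0%, 6.53%, 6.25% and 5.82%).

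The 3 libraries of the TMMpro:GFP line were clustered together and the fusion library alone, since line, chemistry and immersion differed. Counts per 10000 were log-transformed and 2000 variable genes were taken by dispersion. In the joint clustering the 4386 genes that differed at least 1.5-fold between libraries were left out, and genes were centred and scaled per library. Then came 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 with seed 0 (leidenalg 0.10.2, igraph 0.11.9), which gave 23 joint clusters and 26 fusion clusters. A cluster was named from the 8 marker lists if at least 3 markers were 2-fold above all other cells (1.5-fold in the fusion library). The marker lists were fixed before the data were examined. The naming rule itself, with its folds and the depth limit given next, was set after the clusters were seen. A cluster with a median depth under 33.3% of its libraries' and no marker among its 10 leading genes stayed unnamed. Guard mother cell-like clusters had more MUTE than FAMA, young guard cell-like ones more FAMA, and lineage clusters led by cell cycle genes were called dividing lineage-like.

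The rule kept out 4 joint clusters. Cluster 2, of shallow cells, held 10.4% of DMSO, 3.76% of BL and 7.92% of BIK. Cluster 14, led by glutathione transferase genes, held 2.24%, 1.91% and 5.83%, cluster 15, led by AOC1 and WRKY18, held 4.95%, 3.18% and 0.904%, and cluster 19 held 2.05%, 1.13% and 1.68%. Mesophyll-like cluster 3 and early lineage-like cluster 16 were also under the depth limit, at 0.227 and 0.295 of their libraries' median. They kept their names because markers were among their leading genes. In the fusion library 53.6% of cells stayed unnamed. Fusion cluster 9 (3.15% of cells) was kept out by hand because its leading genes were not mesophyll genes. Early lineage-like joint clusters were 7, 10 and 16, guard cell-like ones 0, 1, 5, 6, 9 and 12, and mesophyll-like ones 3, 11, 17 and 22. Some named clusters were led by genes outside the marker lists: TPX2, EARLI1 and BGLU11 led mesophyll-like cluster 11, RAB18 and KIN1 led guard cell-like cluster 5, and HSP21 was among the leading genes of cluster 12.

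UMI counts were summed per library, or per class and library for the 7 classes with at least 100 cells in each of the 3 libraries, and scaled to counts per 1000000 UMIs (CPM) over all features. Ratios are log2((CPM + 1)/(CPM + 1)), with an exact conditional binomial interval on the counts. Levels have exact Poisson intervals and shares of cells exact binomial (Clopper-Pearson) intervals, all at 95% and for counting error only. Cells are not replicates, so no test between libraries was made, and neither p-values nor standard errors are given. Genes with a mean of at least 10 CPM over the compared libraries were counted when at least 2-fold apart. A count of 0 was treated as up to 3 counts for bounds.

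The 29 gene lists covered 8 sets of cell type markers, S phase, G2 and M phase, brassinosteroid synthesis, inactivation, signalling, induced and repressed genes, sterol synthesis, early auxin response, type-A response regulators, gibberellin, abscisic acid and dehydration, stomatal development, cellulose synthesis and microtubules, wound and protoplasting, heat shock, photosynthesis, expansins, XTH genes, SAUR genes, and genes with RPL or RPS symbols, which include some plastid ribosomal proteins. A list's median over members of at least 1 CPM was placed among 10000 random lists of the same size, matched in 20 bins of expression, as a description of these libraries and not a test. Named genes were the 12 highest and 12 lowest genes with a symbol for BL and for BIK against DMSO (5 and 5 for BL against BIK), up to 4 members per list by absolute ratio, all brassinosteroid synthesis and inactivation genes, and within classes the synthesis genes, BAS1 and the 3 highest and 3 lowest symbols. Across classes, signalling genes with at least 10 CPM in some class were named. Genes without a symbol were skipped, 22 above and 9 below in the range of the named genes of BL and 24 and 10 in that of BIK.

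The similarity of the BL and BIK ratios was set against 100 simulations in which all 3 libraries had the DMSO profile and Poisson noise only. For shares of cells with a UMI, each cell was also thinned to 3000 UMIs and shallower cells were left out. The pipeline was tested on simulated data with known ratios. For BL with DMSO at whole-library depth, 0 of 8851 unchanged genes came out at least 2-fold apart, 94.6% of intervals held the true ratio, and all 67 genes set 2.5-fold apart were found. At the depth of the young guard cell-like class, 5 of 8842 unchanged genes came out at least 2-fold apart and 91.0% of 67 genes set 2.5-fold apart were found.

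Alternatives tried were pseudocounts of 0.1 and 5 CPM, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, organelle genes left out of the total, all deposited barcodes, cells of at least 1000 genes, means of per-cell CPM, every class at its DMSO weight, other CPM minimums, clustering resolutions of 0.5 and 1.5, doublets kept, no centring, the variable genes that differed between libraries kept, and DMSO cells split at random into a pair of equal sets, each used in a single comparison. Giving every cluster its DMSO weight, in the whole library and within classes, was added after seeing the data. Transposable element loci were counted in the totals but left out of the gene comparisons. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.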

Results

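RNA was counted in single protoplasts of Arabidopsis thaliana Col-0, prepared from shoots of seedlings 5 days old and sorted by GFP. GFP marks cells in which the promoter of TOO MANY MOUTHS (TMM, AT1G80080), a receptor-like protein of the stomatal lineage, is active. Each of the 4 groups held 1 library. An untreated library came from the TMMpro:TMM-GFP fusion line. The other 3 came from the TMMpro:GFP line, immersed for 2 h in 0.1% DMSO, in 1 µM brassinolide (BL, the most active brassinosteroid) or in 50 µM bikinin (BIK, an inhibitor of the GSK3-type kinases that repress brassinosteroid signalling). The series title concerns brassinosteroid signalling in particular cell types before the asymmetric division that starts stomatal development. With 1 library per group no test between groups was possible, and all intervals below are 95% intervals for counting error only.

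After filtering, 12215 cells remained in the fusion library, 7620 in DMSO, 7320 in BL and 6858 in BIK. Their summed UMI counts were 65577319, 72708214, 77075006 and 63366833, and the median cell held 2812, 6852, 8396.5 and 6002.5 UMIs. TMM itself stood at 387 counts per 1000000 UMIs (CPM) in the fusion library, 135 in DMSO, 214 in BL and 124 in BIK. The fusion transgene carries the TMM coding sequence, so its reads cannot be told from those of the native gene. Among the stomatal classes of the DMSO library TMM was highest in guard mother cell-like cells (685 CPM) and early lineage-like cells (598 CPM), and it stood at 24.8 CPM in guard cell-like cells. Early lineage-like cells held 769 CPM in BL and 347 CPM in BIK, against 598 CPM in DMSO. In epidermis-like cells the level was 155 CPM in BL and 8.19 CPM in BIK, beside 38.9 CPM in DMSO.

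The share of early lineage-like cells with a TMM UMI was 56.1% in DMSO, 65.1% in BL and 41.6% in BIK, at median depths of 5072.5, 6776.5 and 5298 UMIs. Mesophyll-like cells, which should lack TMM, gave 2.17%, 3.04% and 1.35% at median depths of 3512.5, 8886 and 2845 UMIs. With each cell thinned to 3000 UMIs the early lineage-like shares were 55.6%, 68.1% and 41.6%, and the mesophyll-like shares were 0.754%, 0.590% and 0.199%. Thinning left out 247, 235 and 327 early lineage-like cells of the DMSO, BL and BIK libraries.

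Cell classes were compared between the 3 libraries of the TMMpro:GFP line to see which cells each sorted pool held. Guard cell-like cells, marked by genes such as the myrosinase TGG1 and the channel KAT1, made up 51.0% of the BL library (49.8% to 52.1%, 3730 cells). Their share was 31.3% in DMSO (30.2% to 32.3%, 2383 cells) and 36.7% in BIK (35.6% to 37.9%, 2518 cells). Early lineage-like cells, marked by SPCH and EPF2, made up 9.90% of DMSO (9.23% to 10.6%), 13.1% of BL (12.3% to 13.9%) and 14.5% of BIK (13.6% to 15.3%). Mesophyll-like cells were 19.3% of DMSO (18.5% to 20.25%), 7.19% of BL (6.60% to 7.80%) and 15.1% of BIK (14.3% to 16.0%). Vasculature-like cells were 2.09% of DMSO, 0.410% of BL and 0.714% of BIK. Guard mother cell-like cells, marked by MUTE, were 5.16%, 4.88% and 3.78% of DMSO, BL and BIK, and dividing lineage-like cells were 3.02%, 3.62% and 3.35%. Young guard cell-like cells made up 2.76%, 3.52% and 3.82%, epidermis-like cells 6.84%, 6.33% and 5.75%, and unnamed cells 19.6%, 9.99% and 16.3%. MUTE stood at 390 CPM in guard mother cell-like cluster 8, 410 CPM in dividing lineage-like cluster 20 and 174 CPM in early lineage-like cluster 16. FAMA stood at 941 CPM in dividing lineage-like cluster 18. The early, dividing and guard mother cell-like classes are therefore not cleanly separated stages. The GFP sort sets which cells enter each pool, and median depth differed between classes and libraries. The shares depended on the clustering. Vasculature-like cells were 4.09%, 1.53% and 2.41% of DMSO, BL and BIK at a resolution of 0.5, and epidermis-like cells 5.66%, 3.68% and 3.27% with doublets kept. With the genes that differed between libraries kept in the clustering, epidermis-like cells were 5.47%, 7.23% and 8.06%, BIK then being highest, and dividing lineage-like cells 3.37%, 3.70% and 3.83%. No cluster was named guard mother cell-like in that clustering. Guard mother cell-like cells were 4.00%, 5.25% and 3.95% without per-library centring, BL then being highest. Young guard cell-like cells were 4.00%, 4.53% and 3.89% with doublets kept, BIK then being lowest, and unnamed cells 36.0%, 18.0% and 32.4%. With doublets kept, early lineage-like cells were 5.30%, 10.9% and 8.88% of DMSO, BL and BIK, and without per-library centring they were 12.4%, 14.97% and 9.62%, the lowest share then lying in BIK. At a resolution of 0.5 they were 21.6%, 23.0% and 19.2%, BIK again being lowest. No cluster was named guard mother cell-like or epidermis-like at that resolution, so the early lineage-like class there need not hold the same cells. The same holds for values of early lineage-like cells given below at a lower clustering resolution. Mesophyll-like cells were 8.48%, 5.30% and 6.85% with doublets kept, and 9.55%, 4.49% and 7.31% without centring.

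**Figure D1:**
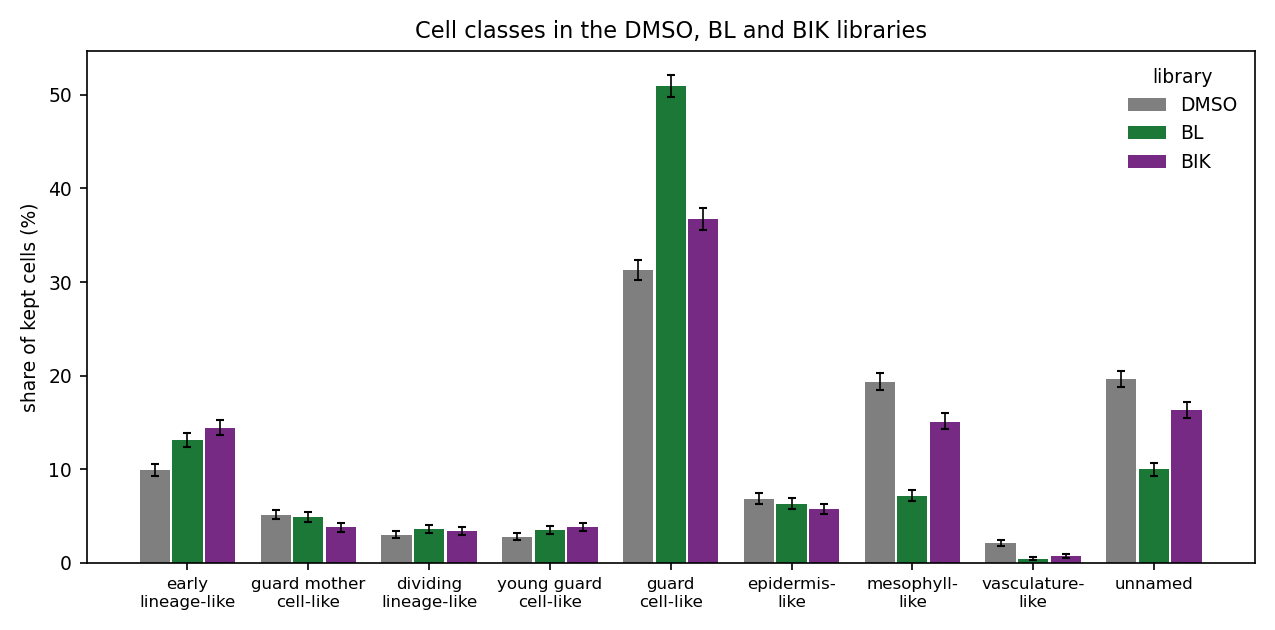
Share of kept cells (%) in each cell class for the DMSO (gray), BL (green) and BIK (purple) libraries, 1 library each; bars are shares and lines are exact binomial 95% intervals. Guard cell-like cells stand at 31.3% in DMSO, 51.0% in BL and 36.7% in BIK, and mesophyll-like cells at 19.3%, 7.19% and 15.1%.

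BL was set against DMSO to ask which transcripts differ after the hormone is added. Among the 12 highest named genes, AGP4 (AT5G10430) and AGP7 (AT5G65390), arabinogalactan proteins of the cell wall, had log2 ratios of 2.34 (2.21 to 2.46) and 1.40. RGF9 (AT5G64770), the precursor of a growth peptide, reached 2.06 (1.92 to 2.20), and SAUR63 (AT1G29440), a small auxin up RNA that promotes organ elongation, reached 1.98 (1.86 to 2.097). At the other end UGT76E12 (AT3G46660), a glycosyltransferase, had 0.545 CPM in BL and 22.9 CPM in DMSO, a log2 ratio of -3.95 (-4.11 to -3.77). The transcription factor RAP2.6 (AT1G43160) and the phytosulfokine precursor PSK2 (AT2G22860) were lower as well, at -2.94 and -2.57.

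The other high genes of the 12 were LSU2 (AT5G24660, 1.97), a low-sulfur response gene; DCF (AT3G48720, 1.76), an enzyme of cutin; the small GTPase RABA2b (AT1G07410, 1.65); MLP423 (AT1G24020, 1.56); the ascorbate peroxidase APX2 (AT3G09640, 1.55); the chloroplast chaperone HSP21 (AT4G27670, 1.48); MYB4 (AT4G38620, 1.37), a repressor of phenylpropanoid synthesis; and ST2B (AT5G07000, 1.36). With every cell given the same weight the AGP4 log2 ratio was 0.32 and that of MLP423 0.89. With every cluster at its DMSO weight DCF stood at 1.12, MYB4 at 0.87 and ST2B at 0.90, and with every class at its DMSO weight HSP21 at 0.97. The remaining low genes were the metallothionein MT3 (AT3G15353, -3.77), the efflux carrier DTX1 (AT2G04040, -3.32), the peroxiredoxin TPX2 (AT1G65970, -2.83), BGLU11 (AT1G02850, -2.65), MYB15 (AT3G23250, -2.42), FMO GS-OX4 (AT1G62570, -2.38), CYP71A22 (AT3G48310, -2.30), the inositol synthesis enzyme MIPS1 (AT4G39800, -2.28) and the sulfotransferase SOT12 (AT2G03760, -2.24). Several of these mark cells that were fewer in BL. MT3 led the vasculature-like cluster, and TPX2, BGLU11 and DTX1 were among the leading genes of mesophyll-like cluster 11, which held 6.26% of DMSO and 1.82% of BL cells. Among all deposited barcodes MT3 stood at -2.04. With every cluster at its DMSO weight MT3 stood at -2.51, DTX1 at -1.92, TPX2 at -1.02, BGLU11 at -1.07, MYB15 at -1.001 CYP71A22 at -1.04, SOT12 at -1.35 and FMO GS-OX4 at -0.63, while PSK2 stood at -2.62 and RAP2.6 at -2.77. The counting intervals of the 24 genes reached at most 0.18 to either side.

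Of 9287 genes with a mean of at least 10 CPM, 136 were at least 2-fold higher and 181 at least 2-fold lower in BL, so 42.9% of these genes were higher. Simulated counting noise alone gave 0 such genes. With TMM scaling factors, a normalization method unrelated to the gene, the split was 107 higher and 218 lower (32.9% higher). With every class at its DMSO weight 71 were higher and 132 lower, of which 44 and 106 were among the genes above. With every cluster at its DMSO weight, an alternative chosen after seeing the data, 57 were higher and 88 lower.

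Genes of brassinosteroid synthesis were lower in BL, with a list median log2 ratio of -1.23 over 5 measured members (percentile 0.01 among 10000 random lists matched on expression). The cytochrome P450 enzymes BR6OX2 (AT3G30180, 33 UMIs in BL and 283 in DMSO) and ROT3 (AT4G36380, 8 and 147 UMIs) had log2 ratios of -1.78 (-1.95 to -1.57) and -1.45 (-1.56 to -1.28). DWF4 (AT3G50660), which catalyses the rate-limiting hydroxylation, stood at -1.23 (-1.42 to -1.03). CYP90D1 (AT3G13730) had 0 UMIs in BL and 64 in DMSO and was at least 22.6-fold lower, but 39 of the 64 were in vasculature-like cells, which were fewer in BL. CPD (AT5G05690) had 99.5 CPM in BL and 111 CPM in DMSO, a log2 ratio of -0.15 (-0.20 to -0.11). That ratio was -0.60 with classes and -0.58 with clusters at DMSO weights, and 0.06 with every cell given the same weight. The reductase DET2 (AT2G38050) stood at -0.09 (-0.29 to 0.11), 0.06 with classes and 0.15 with clusters at DMSO weights. Most members had few UMIs, and a pseudocount of 5 CPM brought the median to -0.46, BR6OX2 to -0.71, DWF4 to -0.66 and ROT3 to -0.46. That pseudocount reduced the ratios of 22 of 67 named genes by over 1.5 times in BL and of 16 of 66 in BIK, among them UGT76E12 (-2.33), XTH15 (-1.77) and GH3.5 (-0.76) in BL and PNP-A (1.08), IAA29 (-0.82), PRE1 (0.82) and NCED3 (-0.79) in BIK.

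Among genes that inactivate brassinosteroids, the P450 BAS1 (AT2G26710) was higher in BL, at 11.7 CPM against 6.62 CPM (log2 ratio 0.74, 0.60 to 0.89), and BEN1 (AT2G45400) stood at 0.59 (0.23 with classes and 0.19 with clusters at DMSO weights). The glucosyltransferase genes UGT73C6 (AT2G36790) and UGT73C5 (AT2G36800) stood at -1.85 and -0.87, and at -0.73 and 0.15 with clusters at DMSO weights. With classes at DMSO weights UGT73C6 stood at -1.19. SOB7 (AT1G17060), a P450 related to BAS1, was at 0.14, and below 0 with classes at DMSO weights (-0.04), with clusters at DMSO weights (-0.06) and with equal cell weights (-0.17). The list median was 0.14 over 5 members, and it turned to -0.04 with classes at DMSO weights and to -0.17 with equal cell weights. Signalling components had a median of -0.01 over 18 members, 0.01 among cells of at least 1000 genes, -0.12 with classes at DMSO weights and -0.15 with equal cell weights, with the transcription factor BEH2 (AT4G36780) at -1.78 and the receptor BRI1 (AT4G39400) at -0.84. Of 18 genes known from the literature to be induced by brassinosteroids 14 were higher and 4 lower, with a median of 0.40 (0.17 with equal cell weights). EXPA8, an expansin that loosens the wall, stood at 1.54 and SAUR15 at 1.36 (0.86 and 0.50 with a pseudocount of 5 CPM), while XTH24, a xyloglucan-modifying enzyme, stood at -2.01 (-1.23 with clusters at DMSO weights). Genes known to be repressed had a median of -0.08 over 7 members, -0.37 with classes at DMSO weights, -0.28 with clusters at DMSO weights and -0.37 with equal cell weights, with the MYB-type repressor MYBL2 at -1.37.

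The median of all genes was 0.08 in BL, with quartiles of -0.15 and 0.28. Of 47 SAUR genes 29 were higher and 18 lower (median 0.65, percentile 100, 0.33 with a pseudocount of 5 CPM, 0.43 with clusters at DMSO weights), and 16 and 2 of them passed 2-fold. Expansins had a median of 0.49 with 15 of 20 higher (percentile 100, 0.25 with equal cell weights), and EXPA17 had 418 UMIs in BL and 0 in DMSO, so the pseudocount sets its log2 ratio (5.79 at 0.1 CPM, 1.06 at 5 CPM, and 0.26 at the main pseudocount with equal cell weights). XTH genes had a median of 0.14 with 15 of 21 higher, within the middle 95% of random lists (percentile 84.4), 0.02 with classes at DMSO weights, and ranged from XTH15 at -2.94 to XTH16 at 1.16 (0.43 with clusters at DMSO weights). All 15 genes of cellulose synthesis and microtubules were higher (median 0.35, 0.18 with equal cell weights), and the 12 sterol synthesis genes had a median of 0.37 (0.21 with classes at DMSO weights). S phase genes were higher in 15 of 15 members (median 0.36, 0.57 with clusters at DMSO weights, 0.20 with a pseudocount of 5 CPM). G2 and M phase genes were higher in 19 of 19 (median 0.50, 0.28 with classes at DMSO weights).

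Hormone and stress lists differed in direction. Early auxin response genes had a median of -0.36 with 7 of 10 lower (-0.20 with a pseudocount of 5 CPM). Among them GH3.5 stood at -1.48 and GH3.6 at -1.39 (-0.81 with classes at DMSO weights), enzymes that conjugate auxin. Type-A cytokinin response regulators had a list median of -0.33 (-0.12 with equal cell weights), with ARR6 at -1.82 (-1.17 with classes at DMSO weights). Wound and protoplasting genes were lower in 13 of 17 (median -0.23, -0.39 with equal cell weights), with WRKY40 at 206 CPM in BL and 527 CPM in DMSO. Heat shock genes were higher in 10 of 10 (median 0.55, 0.21 with classes at DMSO weights), with HSP18.2 at 2142 CPM and 938 CPM (log2 ratio 1.19, 0.68 with classes at DMSO weights). Abscisic acid and dehydration genes had -0.12 (-0.27 with classes at DMSO weights, -0.04 with equal cell weights), and gibberellin genes -0.04, which turned to 0.13 with classes at DMSO weights, 0.07 with clusters at DMSO weights and 0.42 with equal cell weights. Genes with RPL or RPS symbols, ribosomal proteins, had -0.08, and 0.09 with classes at DMSO weights. Stomatal development regulators had 0.19 over 24 members, 0.05 with classes at DMSO weights.

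Marker lists differed along with the class shares. Guard cell markers were higher in BL in 11 of 11 members (median 0.86), with the channel GORK at 1.08 and the kinase HT1 at 1.05. Classes at DMSO weights brought that median to 0.33 and clusters at DMSO weights to 0.11, with GORK at 0.59 and HT1 at 0.37. Early lineage markers stood at 0.60, guard mother and young guard markers at 0.20, and epidermis markers at 0.83, with CYP77A6 at 1.19 (0.56 with clusters at DMSO weights) and BDG1 at 1.14 (medians 0.39, 0.04 and 0.53 with classes at DMSO weights). Vasculature markers stood at -1.42, and -0.69 with classes at DMSO weights, and the sugar transporter SWEET11 at -1.60, which turned to 0.31 under both weightings. Mesophyll markers stood at -0.60 and 18 of 18 photosynthesis genes were lower (median -0.52). Both medians turned to 0.24 with classes at DMSO weights, and with clusters at DMSO weights photosynthesis genes stood at 0.16 and mesophyll markers at -0.02. The 2 measured trichome markers had a median of -0.45, and ANT, the only measured marker of meristem and leaf primordium, stood at -0.82.

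BIK was set against DMSO to ask which transcripts differ when GSK3-type kinases are inhibited below the receptor. Among the 12 highest named genes, IGMT3 (AT1G21110) and IGMT2 (AT1G21120), methyltransferases of indole glucosinolates, had log2 ratios of 2.45 (2.31 to 2.58) and 2.16 (2.06 to 2.27). LACS1 (AT2G47240), KCS3 (AT1G07720) and DCF, enzymes of cuticular lipids, had 1.49, 1.52 and 1.73, and XTH16 (AT3G23730) had 855 CPM in BIK and 263 CPM in DMSO (1.70, 1.68 to 1.72). The arabinogalactan protein AGP2 (AT2G22470) was lowest, at 11.6 CPM against 114 CPM (-3.18, -3.28 to -3.08), followed by the late embryogenesis protein LEA14 (AT1G01470) at -2.84 and ELI3-2 (AT4G37990), an elicitor-activated dehydrogenase, at -2.75.

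The other high genes were the defence regulator ACD6 (AT4G14400, 1.92), MLP423 (1.58), RGF9 (1.48), the peptide transporter OPT1 (AT5G55930, 1.47), the receptor-like kinase RKL1 (AT1G48480, 1.47) and GAT1_2.1 (AT1G15040, 1.45). With clusters at DMSO weights DCF stood at 0.92, XTH16 at 0.87 and KCS3 at 0.80. The other low genes were RAP2.6 (-2.59), MYB74 (AT4G05100, -2.41), PSK2 (-2.41), UGT76E12 (-2.41), the jasmonate synthesis enzyme AOC3 (AT3G25780, -2.36), the Nudix hydrolases NUDX25 (AT1G30110, -2.28) and NUDT18 (AT1G14860, -1.99), the auxin response repressor IAA2 (AT3G23030, -2.08) and the jasmonate response repressor JAZ3 (AT3G17860, -1.91). The counting intervals of the 24 genes reached at most 0.16 to either side.

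In all, 174 of 9472 genes were at least 2-fold higher and 160 at least 2-fold lower in BIK (52.1% higher), where simulated counting noise gave 0. This split rested on the scaling. TMM factors moved the median of all genes from 0.14 to -0.06 and gave 93 higher and 266 lower (25.9% higher). With classes at DMSO weights 124 were higher and 137 lower, 105 and 126 of them among the genes above. Clusters at DMSO weights gave 75 and 112.

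Brassinosteroid synthesis genes were lower in BIK as well, with a median of -1.22 over 5 members (percentile 0, -1.30 with TMM factors, -0.60 with a pseudocount of 5 CPM). BR6OX2 had 55 UMIs against 283 (-1.39), DWF4 121 against 446 (-1.29), ROT3 19 against 147 (-1.22), and CPD stood at 69.6 CPM against 111 CPM (-0.66), with DET2 at 0.03 (-0.13 with TMM factors). Genes that inactivate brassinosteroids had a median of 0.02 over 5 members, -0.18 with TMM factors and -0.24 with clusters at DMSO weights. BAS1 stood at 0.07, SOB7 at 0.02, BEN1 at -0.22 (-0.11, -0.18 and -0.43 with TMM factors, and -0.24, -0.18 and -0.47 with clusters at DMSO weights), UGT73C6 at -0.82, and UGT73C5 at 0.12 (-0.08 with TMM factors). Signalling components had 0.19, and -0.02 with TMM factors, with BEH2 at -1.87 and the co-receptor SERK1 at 0.96. Of 17 brassinosteroid-induced genes 11 were higher and 6 lower (median 0.51, 0.32 with TMM factors), among them PRE1, a growth-promoting HLH factor, at 1.37 and XTH24 at -1.14, and the repressed genes had -0.04 over 7 members, -0.24 with TMM factors and -0.30 with classes at DMSO weights.

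Abscisic acid, auxin and heat shock genes were lower in BIK. The abscisic acid and dehydration list had a median of -0.93 with 9 of 12 lower (percentile 0; -0.45 with a pseudocount of 5 CPM), among them KIN2 at 134 CPM against 425 CPM (-1.65), RAB18 at 26.3 CPM against 83.8 CPM (-1.64) and NCED3, an abscisic acid synthesis enzyme, at -1.36. Early auxin genes had -0.65 with 8 of 10 lower (-0.34 with a pseudocount of 5 CPM), IAA29 standing at -1.70. Type-A regulators had a list median of -0.53 (-0.24 with equal cell weights), with ARR6 at -2.05 (-1.07 with a pseudocount of 5 CPM). Heat shock genes were lower in 10 of 10 (median -0.53), with HSP17.4 at 924 CPM against 1911 CPM, and wound and protoplasting genes in 12 of 17 (median -0.47, -0.28 with classes at DMSO weights). Gibberellin genes had 0.45 (0.16 with clusters at DMSO weights).

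Among growth families in BIK, expansins had a median of 0.51 with 12 of 17 higher, and PNP-A, an expansin-like natriuretic peptide, stood at 2.02 (list median 0.29 with equal cell weights). SAUR genes had -0.01 with 21 higher and 22 lower, and the median turned to 0.01 among cells of at least 1000 genes and to 0.03 with classes at DMSO weights. XTH genes had -0.13 with 13 of 20 lower (-0.31 with TMM factors). All 15 genes of cellulose synthesis and microtubules were higher (median 0.49, 0.28 with TMM factors), and sterol synthesis genes had 0.35 (0.15 with TMM factors). S phase genes were higher in 14 of 15 (median 0.25, percentile 68.9, 0.07 with TMM factors), G2 and M phase genes in 18 of 19 (median 0.50, 0.33 with TMM factors and 0.08 with clusters at DMSO weights). RPL and RPS genes were higher in 47 of 56 at a median of 0.18, which turned to -0.03 with TMM factors.

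Guard cell and epidermis markers stood at 0.79 and 0.84 in BIK beside these lists, with KAT1 at 1.28, FDH, a synthase of cuticular lipids, at 1.03, and with clusters at DMSO weights a guard cell median of 0.47 and KAT1 at 0.51. Early lineage markers had -0.02, and -0.21 with TMM factors, -0.28 with classes at DMSO weights, -0.34 with clusters at DMSO weights and -0.32 with equal cell weights. Stomatal regulators had 0.08, -0.11 with TMM factors and -0.03 with classes at DMSO weights, with the division-limiting peptide EPF2 (AT1G34245) at 21.5 CPM against 54.9 CPM (-1.31) and the protease SDD1 at 1.198 (0.60 with clusters at DMSO weights). Guard mother and young guard markers had 0.04, -0.16 with TMM factors and -0.31 with clusters at DMSO weights. Mesophyll markers had -0.11 and photosynthesis genes -0.09, which turned to 0.12 and 0.14 with classes at DMSO weights and stood at -0.32 and -0.30 with TMM factors. Vasculature markers had -0.65, -1.44 with equal cell weights, which turned to 0.35 with classes and with clusters at DMSO weights. The 3 measured trichome markers had 0.57, and -0.02 with clusters at DMSO weights, and ANT stood at 0.40.

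Within classes, the lower level of brassinosteroid synthesis genes in BL was largest in epidermis-like and early lineage-like cells. In early lineage-like cells CPD stood at 13.9 CPM in BL and 57.1 CPM in DMSO, a log2 ratio of -1.96 (-2.30 to -1.63), and BR6OX2 had 7 UMIs against 44 (-2.42, -3.05 to -1.67). DWF4 had 0 UMIs against 22 and was at least 11.1-fold lower, and ROT3 had 0 against 18 and was at least 9.12-fold lower. In epidermis-like cells DWF4 had 1 UMI against 122 (-4.62, -4.88 to -3.79) and CPD stood at 21.4 CPM against 83.4 CPM (-1.91, -2.22 to -1.61). The epidermis-like class was cluster 4 alone, so no clusters within it could be put at DMSO weights. TMM and early lineage markers also differed between its BL and DMSO cells. A different make-up of this class and a lower level within its cells cannot be told apart. Guard cell-like cells, where CPD was highest in DMSO, held 204 CPM in BL and 245 CPM in DMSO (-0.27, -0.32 to -0.21). DWF4 stood there at 4.42 CPM in BL and 9.49 CPM in DMSO (-0.95, -1.22 to -0.68), and at -0.79 in BIK. Different clusters held the largest part of that class: cluster 1 in DMSO (33.0%) and cluster 0 in BL (28.6%) and BIK (27.8%).

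The list median for synthesis genes in BL was -2.33 in early lineage-like cells, or -1.96 with members at 0 set to 3 counts and -0.99 with a pseudocount of 5 CPM. It was -3.63 in epidermis-like, -1.54 in mesophyll-like, -0.95 in dividing lineage-like (-0.61 with a pseudocount of 5 CPM), -0.84 in guard mother cell-like, -0.41 in young guard cell-like and -0.27 in guard cell-like cells. The corresponding BIK medians were -1.76, -3.52, -1.13, -0.86, -0.55, -0.73 and -0.53, the last -0.83 with TMM factors within the class. Members under a mean of 1 CPM were left out class by class, so these medians do not cover the same genes. In guard cell-like cells of DMSO, BR6OX2 stood at 0.235 CPM and ROT3 at 0.188 CPM, and the median of the class is the CPD ratio. In young guard cell-like cells of DMSO, DWF4, BR6OX2 and ROT3 stood at 0 CPM and could not be lower. In BIK, CPD stood at -1.03 (-1.31 to -0.75) in early lineage-like cells, -2.40 (-2.82 to -2.004) in epidermis-like and -0.53 (-0.59 to -0.47) in guard cell-like cells. BAS1 stood at 46.1 CPM in BL, 23.5 CPM in BIK and 27.0 CPM in DMSO in early lineage-like cells (0.75, 0.45 to 1.06, for BL and -0.19 for BIK). No difference between classes was tested, because each class had 1 value per library.

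**Figure D2:**
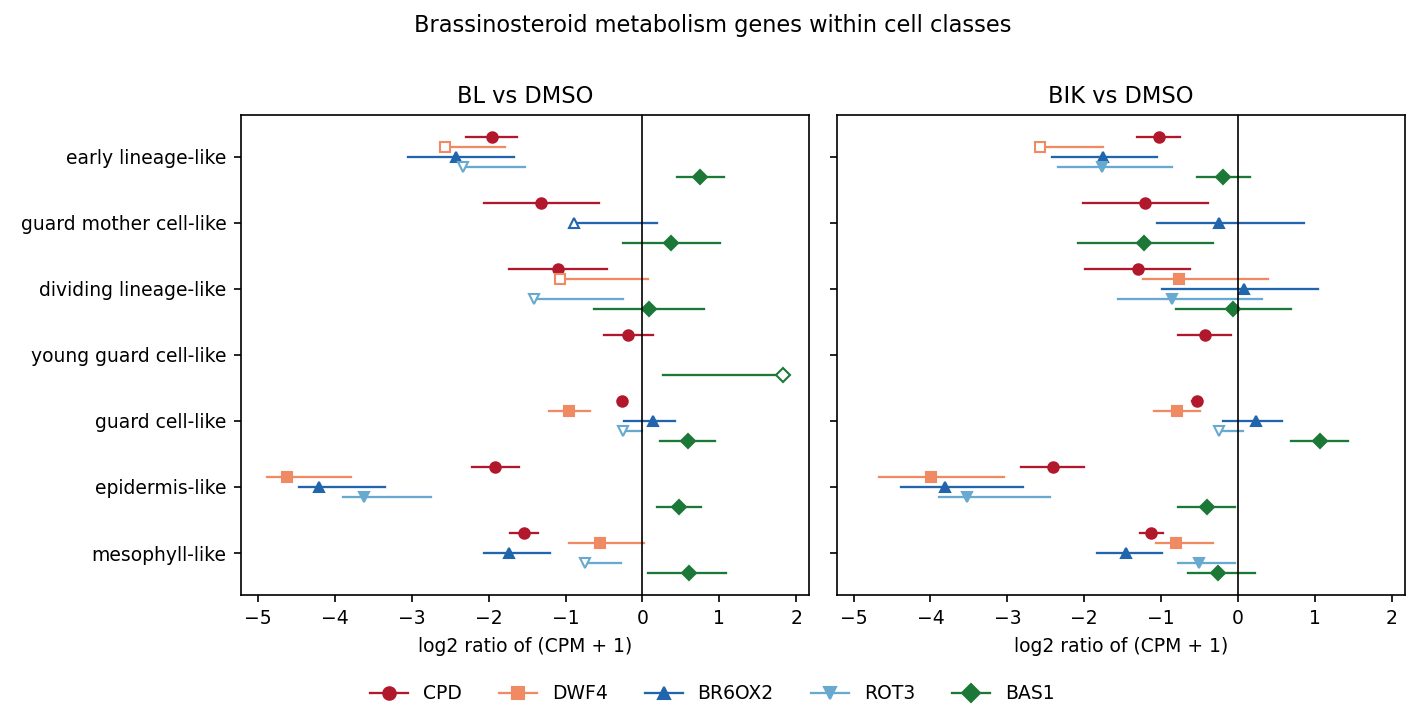
Log2 ratio of (CPM + 1) for CPD, DWF4, BR6OX2, ROT3 (synthesis) and BAS1 (inactivation) within 7 cell classes, BL against DMSO on the left and BIK against DMSO on the right; lines are 95% counting intervals, and open symbols mark genes with 0 UMIs in a library, whose ratio depends on the pseudocount. CPD lies at -1.96 in early lineage-like and at -0.27 in guard cell-like cells of BL, and genes with at most 3 UMIs in both libraries are not drawn.

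In early lineage-like cells of the BL library, SAUR genes were higher in 32 of 44 (median 0.90), S phase genes in 12 of 15 (median 0.86, 0.40 at a lower clustering resolution) and brassinosteroid-induced genes in 13 of 17 (median 0.75, 0.43 with a pseudocount of 5 CPM). DCF at 2.70, the arabinogalactan protein AGP18 at 2.36 and the actin ACT11 at 2.16 were highest, and PSK2 at -4.31, UGT73B4 at -3.498 and BEH2 at -3.40 lowest. Guard mother cell-like cells differed: SAUR genes were lower in 16 of 22 (median -0.51) and brassinosteroid-repressed genes had a median of -0.996. There PHI-1 stood at 2.16, ARAB-1 at 1.72 and EXPA4 at 1.55, against LEA14 at -2.99, GA2OX6, an enzyme that inactivates gibberellin, at -2.90 and AOC3 at -2.81. Dividing lineage-like cells had G2 and M phase genes higher in 19 of 19 (median 0.34) and expansins at 0.63. The lipid transfer protein LTP2 (510 UMIs against 5; 5.52, 4.68 to 6.24), MLP28 (143 against 3; 4.095, 3.16 to 4.76) and MLP423 (3.37) were highest there, and FAF3 (-3.82), the cytokinin-activating enzyme LOG1 (-3.51) and the aquaporin PIP2;8 (-3.35) lowest. LTP2 was among the leading genes of epidermis-like cluster 4 and MLP28 among those of unnamed cluster 2, and DCF, highest in early lineage-like cells, among those of guard cell-like cluster 9.

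Young guard cell-like cells of BL had APX2 at 3.24, LSU2 at 2.86 and cPT4 at 2.06, with GSTF9 at -2.48, ZAT11 at -2.16 and UBC20 at -2.05, and G2 and M phase genes at a median of -0.51 (-0.25 with a pseudocount of 5 CPM). UBC20 was a leading gene of dividing lineage-like cluster 18. In guard cell-like cells LSU2 (1.94), AGP7 (1.83) and RABA2b (1.77) were highest and AGP2 (-1.93), GSTF9 (-1.74) and PSK2 (-1.65) lowest. All 15 cellulose and microtubule genes were higher (median 0.46), guard cell markers were higher in 11 of 11 (median 0.48, 0.23 with clusters of the class at DMSO weights), and brassinosteroid-induced genes stood at -0.10. Epidermis-like cells had AGP7 at 2.67, AGP4 at 2.64 and PR5 at 2.48, of which AGP4 was a leading gene of unnamed cluster 19. The lipid transfer-like gene EARLI1 (AT4G12480) had 6 UMIs against 1048 (-6.83, -7.43 to -6.12) and was a leading gene of mesophyll-like cluster 11, and ACS11 (AT4G08040), an ethylene synthesis enzyme, had 0 against 432. Early lineage markers stood at 1.47 in this class (0.97 with a pseudocount of 5 CPM). The largest cluster of the mesophyll-like cells was cluster 3 in DMSO (55.4%) and cluster 17 in BL (38.4%, beside 35.7% in cluster 3). In those cells RGF9 (3.21), SAUR63 (2.65) and EXL3 (2.19) were highest and UGT76E12 (-3.94), UGT73B4 (-3.77) and IAA2 (-3.56) lowest. Their SAUR genes were higher in 28 of 38 at a median of 0.83 and their brassinosteroid-induced genes in 12 of 16 at 0.88, or 0.45 and 0.49 with clusters of the class at DMSO weights.

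BIK gave another picture in early lineage-like cells. Early lineage markers were lower in 7 of 8 (median -0.66, -0.39 at a lower clustering resolution), stomatal regulators in 16 of 24 (median -0.37, -0.12 at that resolution) and heat shock genes in 10 of 10 (median -1.12). GAT1_2.1 at 2.55, the sulfate reduction enzyme APR1 at 1.99 and TLP-3 at 1.79 were highest, and MYB15 at -4.30, RAP2.6 at -3.36 and LEA14 at -3.30 lowest. In guard mother cell-like cells early auxin genes had -1.66 (-1.19 with members at 0 set to 3 counts) and SAUR genes were lower in 17 of 23 (median -0.79, -0.76 so set, -0.27 with a pseudocount of 5 CPM). The calmodulin-binding IQD gene iqd17 (2.19), KCS19 (1.73) and LTL1 (1.70) led there, and the dehydrin COR47 (-3.65), the auxin-conjugating enzyme GH3.3 (-3.33) and KIN2 (-3.30) were lowest. GAT1_2.1 was also a leading gene of epidermis-like cluster 4, and COR47 of guard cell-like cluster 12. Dividing lineage-like cells had LTP2 at 5.26, BGLU18 at 5.09 and PBP1, a leading gene of unnamed cluster 2, at 3.64, and GH3.3 at -4.23, the ferritin FER1 at -2.80 and FKD1 at -2.51. Young guard cell-like cells had GH3.3 at 3.23, IGMT4 at 1.93 and GDPD2 at 1.66, and XGD1 at -2.55, CYP81D8 at -2.45 and FIB at -2.42, with G2 and M phase genes lower in 10 of 10 (median -0.93, -0.42 with a pseudocount of 5 CPM).

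Guard cell-like cells of BIK held XTH16 at 1460 CPM against 277 CPM (2.39), COL2 at 2.39 and the phosphate sensor SPX1 at 2.21, and AOC1 at -3.36, AGP2 at -3.28 and ELI3-2 at -3.03. AOC1 was a leading gene of unnamed cluster 15. ELI3-2 was a leading gene of guard cell-like cluster 1, which held 33.0% of the class in DMSO and 16.2% in BIK. Photosynthesis genes were higher in 18 of 18 (median 0.72), cellulose and microtubule genes in 15 of 15 (0.76), SAUR genes in 15 of 22 (0.52) and brassinosteroid-induced genes in 6 of 10 (0.63), while abscisic acid genes stood at -0.79. The median of all genes was itself 0.19 in this class. TMM factors within the class brought these to 0.43, 0.47, 0.27 and 0.33, and clusters at DMSO weights brought photosynthesis genes to 0.29. Clusters 6 and 9, which held 7.55% and 5.37% of the class in DMSO, held 20.6% and 17.43% in BIK. In epidermis-like cells CYP79B2, an enzyme of indole glucosinolate synthesis, had 89 UMIs against 1 (4.41, 3.46 to 4.71), with CYP71A12 at 3.68 and ARPN at 3.55. ACS11 had 0 UMIs there against 432, MYB74 0 against 91, and EARLI1 stood at -5.80. MYB74 was a leading gene of guard cell-like cluster 5 and EARLI1 of mesophyll-like cluster 11. Mesophyll-like cells had IGMT3 (2.86), ACD6 (2.34) and IGMT2 (2.30) highest and RAP2.6 (-3.82), AGP2 (-3.81) and IAA2 (-3.06) lowest, with 6 of 6 type-A regulators lower (median -1.05).

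**Figure D3:**
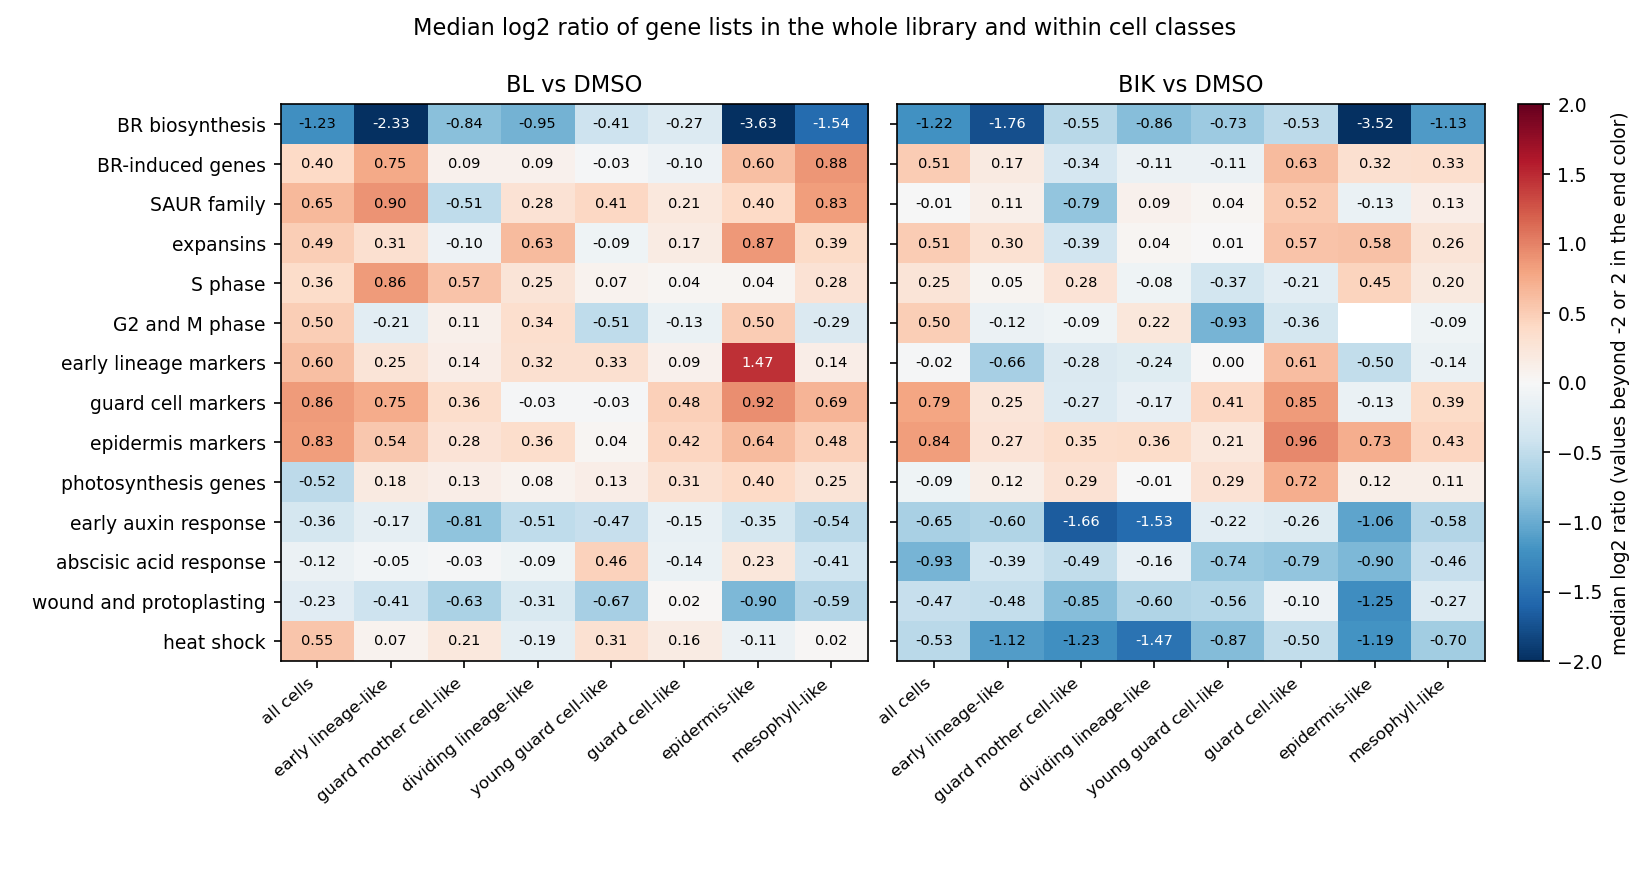
Median log2 ratio of (CPM + 1) of 14 gene lists in the whole library and within 7 cell classes, BL against DMSO on the left and BIK against DMSO on the right; color and number both give the median. SAUR genes stand at 0.90 in early lineage-like and -0.51 in guard mother cell-like cells of BL, and whole-library photosynthesis genes (-0.52 in BL, -0.09 in BIK) turn to 0.24 and 0.14 with classes at DMSO weights.

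BL and BIK were compared with each other because the hormone acts at the receptor and bikinin on the kinases below it. AGP4 had 37.0 CPM in BL and 2.76 CPM in BIK (log2 ratio 3.33, 3.17 to 3.502; 0.87 with equal cell weights). ELI3-2 (2.17), the abscisic acid-induced kinase MAPKKK18 (AT1G05100, 1.87), AGP2 (1.84) and the cytokinin response factor CRF7 (AT1G22985, 1.83) were also higher in BL. TPX2 (-3.60), IGMT2 (-3.28), MT3 (-2.89), IGMT3 (-2.87) and CYP83B1 (AT4G31500, -2.55), an enzyme of indole glucosinolate synthesis, were higher in BIK. Among all deposited barcodes MT3 stood at -1.06, and with clusters at DMSO weights TPX2 stood at -2.28. Heat shock genes had a median of 1.22 (0.73 with clusters at DMSO weights), HSP21 standing at 1.74, and early lineage markers 0.65, EPF2 standing at 1.303. Early auxin genes had 0.51, SAUR genes 0.48, abscisic acid genes 0.35, and brassinosteroid-induced genes 0.27 (0.56 with classes at DMSO weights). With a pseudocount of 5 CPM these medians were 0.19, 0.30, 0.28 and 0.16. Brassinosteroid synthesis genes had 0.07 over 3 members, and -0.05 with equal cell weights. Photosynthesis genes had -0.44 and mesophyll markers -0.42, which turned to 0.09 and 0.12 with classes at DMSO weights, and vasculature markers had -0.86. Of 9608 genes 127 were at least 2-fold higher in BL and 118 in BIK (51.8% higher in BL). TMM factors moved the median of all genes from -0.10 to 0.04 and made the split 214 and 87 (71.1% higher in BL).

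Across 9488 genes the BL and BIK ratios to DMSO had a Pearson r of 0.561 and a Spearman rho of 0.531. Genes are not independent replicates, and both ratios share the DMSO library: libraries simulated without differences gave 0.489 and 0.457. The covariance was 0.104, against 0.000986 in the simulated libraries. Genes at least 2-fold higher in both numbered 71, of 132 in BL and 176 in BIK, where independent lists would share 2.45. Those at least 2-fold lower in both numbered 62, of 179 and 161, against 3.04 for independent lists. A further 4 genes were at least 2-fold apart in opposite directions. DCF, RGF9 and MLP423 were among the genes higher in both, RAP2.6 and PSK2 among those lower in both. The simulations hold counting noise only. Variation of the single DMSO library, which enters both ratios, can give part or all of the excess. Within classes r was 0.563 in early lineage-like cells (0.595 simulated), 0.682 in guard cell-like (0.546), 0.652 in epidermis-like (0.496), 0.622 in mesophyll-like (0.375), 0.634 in dividing lineage-like (0.555), 0.521 in guard mother cell-like (0.462) and 0.406 in young guard cell-like cells (0.5997). The covariance in the same order was 0.109 (0.0161 simulated), 0.121 (0.00330), 0.263 (0.0168), 0.150 (0.00301), 0.109 (0.0195), 0.0867 (0.0154) and 0.0626 (0.0295), so it lay above the simulated value in all 7 classes. In early lineage-like cells 48 genes were at least 2-fold higher in both and 81 lower in both.

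**Figure D4:**
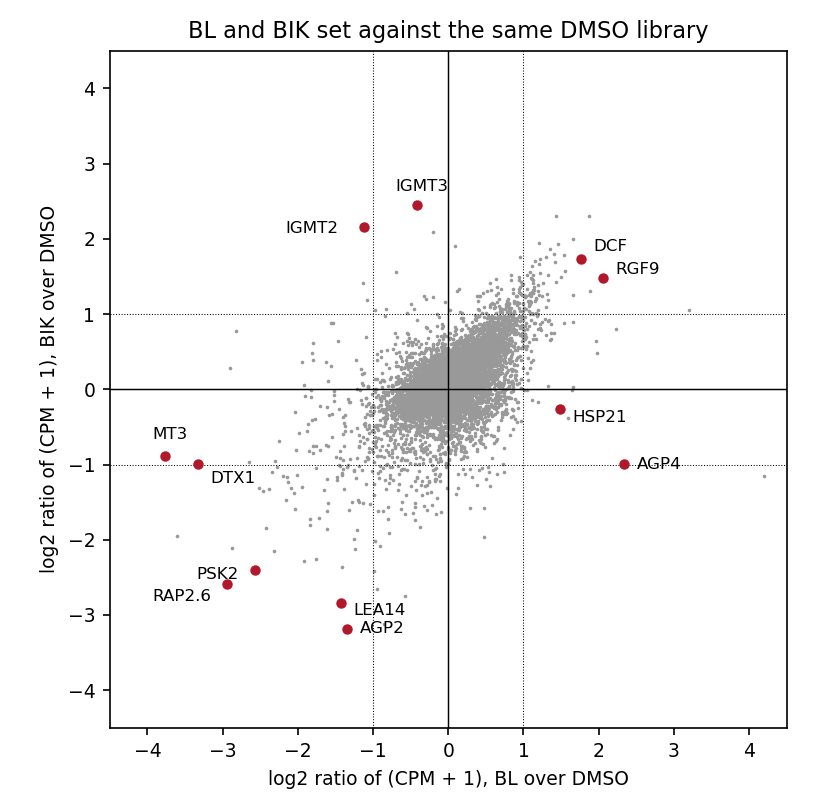
Log2 ratio of (CPM + 1) of BL over DMSO (horizontal) and of BIK over DMSO (vertical) for 9488 genes, 1 point per gene, with dotted lines at 2-fold and 12 named genes in red. DCF and RGF9 lie high in both and RAP2.6 and PSK2 low in both, while AGP4 is high in BL (2.34) and IGMT2 high in BIK (2.16).

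Brassinosteroid genes were then compared across the classes of the DMSO library, to see where the pathway's transcripts lie without added hormone. The receptor gene BRI1 stood at 35.5 CPM in early lineage-like cells (30.2 to 41.5) and 34.7 CPM in epidermis-like cells, against 7.33 CPM in guard cell-like cells (6.22 to 8.57). BES1, a transcription factor of the pathway, was highest in vasculature-like cells (132 CPM) and stood at 87.8 CPM in early lineage-like and 12.5 CPM in guard cell-like cells, whereas its relative BZR1 stood at 39.1 CPM and 73.8 CPM. The GSK3-type kinase gene BIN2 was highest in guard cell-like (185 CPM) and epidermis-like cells (180 CPM) and stood at 143 CPM in early lineage-like cells. Its relative BIL2 was highest in early lineage-like cells (117 CPM; 41.9 CPM in guard cell-like), and BIL1 in dividing lineage-like cells (122 CPM; 33.2 CPM in guard cell-like). BEH1 stood at 13.9 CPM in early lineage-like and 0.431 CPM in guard mother cell-like cells, and BEH3 and BEH4 were highest in young guard cell-like cells (13.6 CPM and 32.7 CPM). Among upstream components the co-receptor BAK1 (60.1 CPM), the kinase BSK3 (24.5 CPM), the phosphatase BSL1 (17.2 CPM) and, downstream, BEH2 (32.6 CPM) were highest in epidermis-like cells, BSK1 in early lineage-like (49.9 CPM) and BSL3 in dividing lineage-like cells (15.1 CPM).

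Metabolism genes were spread unevenly in the same library. CPD was highest in guard cell-like cells (245 CPM) and lowest in guard mother cell-like cells (8.62 CPM), whereas DWF4 (28.4 CPM), BR6OX2 (21.0 CPM) and ROT3 (13.8 CPM) were highest in epidermis-like cells and CYP90D1 in vasculature-like cells (35.7 CPM). BEN1 stood at 429 CPM in guard mother cell-like and 337 CPM in early lineage-like cells and at 2.82 CPM in mesophyll-like cells, and SOB7 at 44.2 CPM in guard mother cell-like and 0.171 CPM in mesophyll-like cells. UGT73C5 (192 CPM) and UGT73C6 (148 CPM) were highest in mesophyll-like cells. In the fusion library BRI1 stood at 10.1 CPM in early lineage-like and 8.19 CPM in guard cell-like cells, BES1 at 82.3 CPM and 52.6 CPM, and BEN1 at 390 CPM in early lineage-like cells. BIN2 was highest there in vasculature-like cells (245 CPM) and lowest in guard mother cell-like cells (59.2 CPM). Vasculature-like cells of the fusion library also held the highest levels of CPD (93.7 CPM), DWF4 (57.1 CPM), BR6OX2 (47.7 CPM), BR6OX1 (27.3 CPM), ROT3 (21.3 CPM), BEH2 (80.9 CPM) and BSK1 (69.9 CPM), and BAK1 was highest in its guard cell-like cells (62.4 CPM). That guard cell-like class held fusion cluster 22 (32.0% of its cells), with FAMA at 790 CPM and HIPP20 and GH9B1 among its leading genes. Young guard cell-like joint cluster 13 also had HIPP20 and GH9B1 among its leading genes, with FAMA at 1015 CPM. The guard cell-like classes of the fusion and DMSO libraries are therefore not matched.

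**Figure D5:**
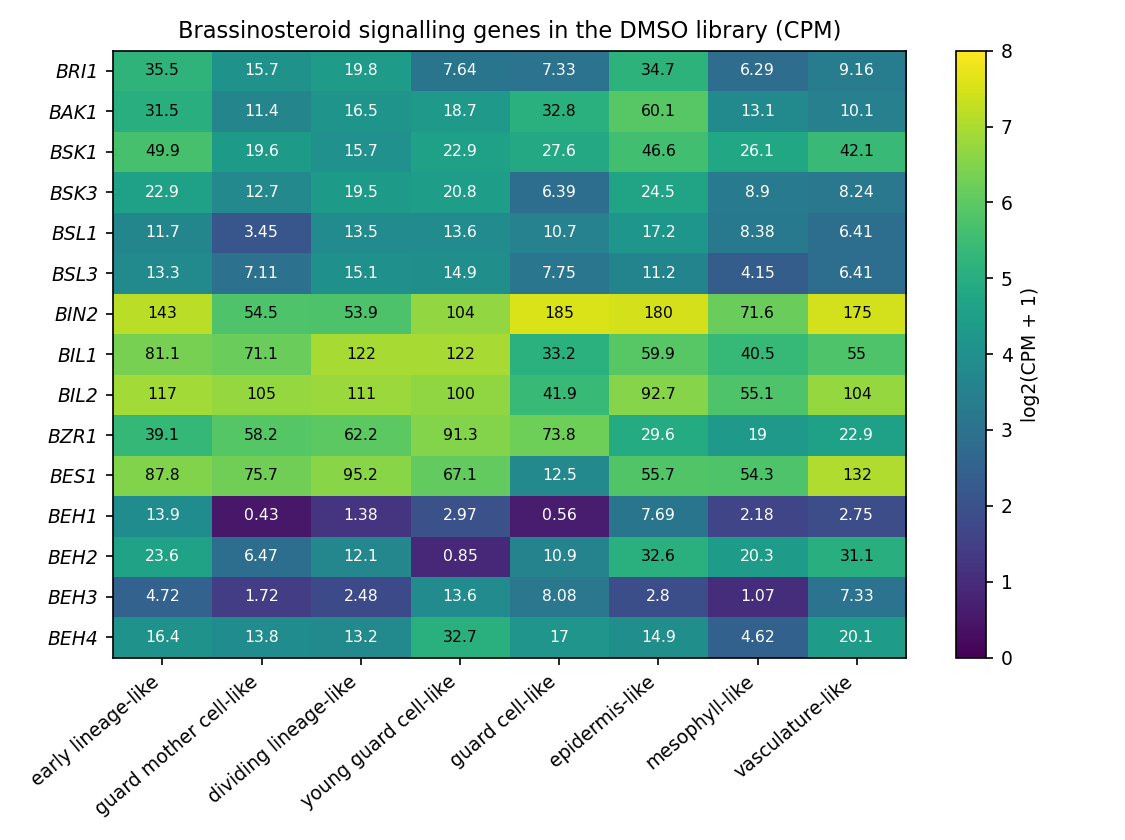
CPM of 15 brassinosteroid signalling genes in 8 cell classes of the DMSO library; each cell of the map prints the CPM, and color gives log2(CPM + 1). BRI1 stands at 35.5 CPM in early lineage-like and 7.33 CPM in guard cell-like cells, and BES1 at 87.8 CPM and 12.5 CPM.

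The untreated fusion library was set beside DMSO as values alone, since line, chemistry, immersion and library differed together. Early lineage markers had a median of 94.4 CPM in the fusion library and 36.3 CPM in DMSO, all 8 of them higher in the fusion library. S phase genes had 20.4 CPM against 4.07 CPM, and G2 and M phase genes 34.9 CPM against 5.64 CPM, with all 15 and all 19 higher. Mesophyll markers had 208 CPM against 2112 CPM, none of 10 higher in the fusion library, and photosynthesis genes 305 CPM against 2428 CPM. Early lineage-like cells were 12.5% of the fusion library, guard mother cell-like 7.28%, dividing lineage-like 10.1%, guard cell-like 5.78% and unnamed cells 53.6%. Cells with at least 3 S phase UMIs were 22.1% of the fusion library, 8.11% of DMSO, 9.66% of BL and 7.58% of BIK, and 21.4%, 3.65%, 4.85% and 4.06% after thinning, which left out 6274, 2463, 1319 and 2331 cells. Mesophyll-like cells gave 7.73%, 8.17% and 6.28% in DMSO, BL and BIK at their own depth, and 1.13%, 1.47% and 1.59% thinned. In thinned early lineage-like cells the shares were 4.14% in DMSO, 9.24% in BL and 4.37% in BIK.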

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

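The tests of the explanations in this part were chosen after the results they examine were seen. No difference between classes given here was tested, since each class had 1 value per library.

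Some results went opposite ways in different classes of the same comparison. The classes set side by side here were picked for their extreme values. The SAUR family median in BIK was 0.52 in guard cell-like and -0.79 in guard mother cell-like cells, a difference of 1.32 on the log2 scale. In BL the SAUR median was 0.90 in early lineage-like (44 members) and -0.51 in guard mother cell-like cells (22 members), 1.41 apart. Members under a mean of 1 CPM were left out class by class, so these medians do not cover the same genes. GH3.3 (AT2G23170), an auxin-conjugating enzyme, stood in BIK at 3.23 in young guard cell-like cells (77 UMIs against 4) and at -4.23 in dividing lineage-like cells (2 UMIs against 96), 7.45 apart. BAS1 stood in BIK at 1.06 (0.69 to 1.43) in guard cell-like and at -1.22 (-2.08 to -0.32) in guard mother cell-like cells, 2.29 apart. With clusters of the class at DMSO weights, BAS1 in guard cell-like cells stood at 0.32 and the SAUR median of BIK there at 0.33.

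Transposable element loci, outside the gene comparisons, took 0.0322% of UMIs in BL (0.0318% to 0.0326%) and 0.0339% in BIK (0.0335% to 0.0344%), above the 0.0293% of DMSO (0.0289% to 0.0297%). The cause of that difference was not tested.

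Guard cell-like cells were 51.0% of the BL library and 31.3% of DMSO. Per cell of another named class they were from 1.23 (1.103 to 1.37, early lineage-like) to 8.30 times (vasculature-like) as many in BL as in DMSO; the former was 0.791 with doublets kept and the latter 4.40 at a resolution of 0.5. Shares do not count sorted cells, so a loss of other cells from the sort and a gain of guard cells cannot be told apart. Among cells of at least 3000 UMIs the shares were 55.0% of 6001 cells and 39.6% of 5157 cells, still 15.4 percentage points apart. A stricter limit on depth thus narrowed the difference but did not remove it. The barcodes already left out for few genes, 1064 in DMSO and 572 in BL, were not covered. With 1 library per treatment, differences of handling between single libraries, among them how well guard cells survived digestion, and an effect of the hormone cannot be told apart.

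Brassinosteroid synthesis genes were lower in BL in early lineage-like cells, while in guard cell-like cells CPD stood at -0.27 and DWF4 at -0.95. A shift between the clusters of the early class does not account for the lower CPD and BR6OX2. With clusters at DMSO weights CPD stood at -2.02 and BR6OX2 at -2.48. The list median of -2.33 could not change under these weights, since its middle member ROT3 had 0 UMIs in BL. The same holds for DWF4, also with 0 UMIs in BL, so neither bears on the question. A shift inside single clusters was not tested. Counting noise is excluded for CPD by the upper end of its interval, -1.63. Free RNA, taken up alike by all droplets of a library, does not account for CPD in guard cell-like cells of BL: the early lineage-like cells held 0.0979 CPD UMIs per cell and guard cell-like cells 1.84, a ratio of 0.0531 (upper bound 0.0665). An effect of the hormone and library handling both stay open, and whether the classes differ in their response was not tested.

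Abscisic acid and dehydration genes were lower in BIK, at a median of -0.93. Class composition does not account for it, since with every class at its DMSO weight the median was -0.94. That weighting does not cover shifts between clusters inside a class. With every cluster at its DMSO weight, an alternative chosen after seeing the data, the median was -0.87. Shifts inside single clusters were not tested. Wound and protoplasting genes (-0.47) and heat shock genes (-0.53) were lower in BIK too, so stress during handling that differed between the libraries and an effect of bikinin cannot be told apart with 1 library each.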

How the results depend on the processing

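The settings below were chosen before the data were examined, except those giving every cluster its DMSO weight. No paired analysis was possible because each group held 1 library and no replicate numbers link the groups. No result had a test, so a gene's ratio or a class share counts as moved where it left its counting interval, a list median where it left the 95% rank interval of its members' median, and a count where it differed over 1.5 times; the cause was not tested unless a sentence names it. A change of sign was counted apart only for lists outside the middle 95% of random lists and for named genes whose counting interval left out no change. Within classes small lists were left out of it too. Other changes of sign lie among the values that stayed or moved. Of 870 list medians under all settings 751 stayed within these limits, 106 moved and 13 were counted as taking the other sign. The numbers were 1159, 111 and 2 of 1272 within classes and 910, 800 and 10 of 1720 for named genes. Of 138 shares of cells under other clusterings or thinned to 3000 UMIs, 74 moved. Depth limits genes with few UMIs, among them most members of the brassinosteroid synthesis list.

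A pseudocount of 0.1 CPM gave the synthesis list a BIK median of -1.63. A pseudocount of 5 CPM, which shrinks ratios of low genes by construction, gave 80 genes at least 2-fold higher in BL and 113 in BIK, 37 higher in both, and a BL median of -0.61 for the synthesis list in dividing lineage-like cells. TMM factors gave 93 higher and 266 lower genes in BIK, 214 higher in BL than in BIK, and in BIK -0.029 for RPL and RPS genes, -0.084 for UGT73C5 and -0.83 for the synthesis list in guard cell-like cells. Median-of-ratios factors gave 93 and 264, 217, -0.026 and -0.080 for the same except the last. Among cells of at least 1000 genes the SAUR median in BIK was 0.011.

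With every class at its DMSO weight, 71 genes were higher in BL and 65 higher in BL than in BIK. The BL values became 0.24 for mesophyll markers, 0.24 for photosynthesis genes, 0.31 for SWEET11 and -0.036 for SOB7, the BIK values 0.35 for vasculature markers and 0.031 for SAUR genes, and BL against BIK 0.12 for mesophyll markers and 0.094 for photosynthesis genes. With every cluster at its DMSO weight, 57 genes were higher and 88 lower in BL, 75 higher in BIK, and 55 higher and 67 lower in BL than in BIK. The BL values became 0.16 for photosynthesis genes, 0.31 for SWEET11, -0.060 for SOB7 and 0.15 for UGT73C5, the BIK values 0.35 for vasculature and -0.024 for trichome markers, and BL against BIK 0.059 for photosynthesis genes. Within classes, mesophyll markers in mesophyll-like cells of BL went from 0.29 to -0.011 and S phase genes in guard cell-like cells of BIK from -0.21 to 0.018. With equal cell weights the BL values were 0.061 for CPD, -0.17 for SOB7 and -0.093 for TUB1, and 205 genes were lower in BL than in BIK.

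The filter on low values set the counts by construction. At a mean of at least 1 CPM the higher and lower genes were 267 and 412 in BL, 308 and 292 in BIK, and 245 and 302 for BL against BIK. With no filter they were 279 and 442, 316 and 319, and 268 and 323. At 50 CPM they were 41 and 69, 68 and 78, and 65 and 43, with r 0.532, rho 0.478, 29 genes higher in both and 22 lower in both. DMSO cells split at random into a pair of equal sets gave r 0.537 and rho 0.492.

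Class shares followed the clustering. At resolution 0.5 early lineage-like cells were 21.6%, 23.0% and 19.2% of DMSO, BL and BIK, and the synthesis list in dividing lineage-like cells of BL stood at -0.80. No cluster was named guard mother cell-like or epidermis-like at that resolution, so its early lineage-like class need not hold the same cells. At resolution 1.5 guard cell-like cells were 29.6% of DMSO, mesophyll-like cells 9.80%, 5.56% and 7.92%, and early lineage-like cells 15.1% of BL and 15.9% of BIK. Without centring early lineage-like cells were 12.4%, 14.97% and 9.62% and mesophyll-like cells 9.55%, 4.49% and 7.31%. With the genes that differed between libraries kept, early lineage-like cells were 12.1% of BIK, and no cluster was named guard mother cell-like. With doublets kept, early lineage-like cells were 5.30%, 10.9% and 8.88%, guard cell-like cells 29.4% of DMSO and 47.7% of BL, and mesophyll-like cells 8.48%, 5.30% and 6.85%.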

Other observations

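In this part, the values with clusters of a class at DMSO weights come from an alternative chosen after the data were seen. The lists placed outside the middle 95% of random lists within a class and not described above give more detail on single classes. Guard cell-like cells of BIK held sterol synthesis genes at a median log2 ratio of 0.51 (0.22 with TMM factors within the class), expansins at 0.57 (0.19 with clusters of the class at DMSO weights), mesophyll markers at 0.69 and epidermis markers at 0.96. In that class 493 of 8540 genes were at least 2-fold higher and 218 lower. The median of all genes was 0.19 there, and the TMM factors of the class were 1.14 in BIK and 0.924 in DMSO. Clusters 6 and 9 held 7.55% and 5.37% of the class in DMSO and 20.6% and 17.43% in BIK. The counts were not repeated with other scaling or cluster weights, so scaling and make-up may account for part of them. In the same class of the BL library, 47 of 8140 genes were at least 2-fold higher and 53 lower. Epidermis-like cells held the most genes apart of the 7 classes in both treatments, 291 higher and 449 lower of 8801 in BL and 365 higher and 572 lower of 9069 in BIK. That class was cluster 4 alone, so a different make-up of the class and changes within its cells cannot be told apart. In those cells gibberellin genes stood at 0.81 in BIK, RPL and RPS genes at 0.49 in BIK and 0.38 in BL, and wound and protoplasting genes at -1.25 and -0.90.

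Early lineage-like cells held 176 genes at least 2-fold higher and 204 lower of 9949 in BL, and 112 and 266 of 10191 in BIK. Gibberellin genes stood at 0.51 in BL and 0.46 in BIK in that class, XTH genes at 0.52 in BL, and type-A regulators at -0.62 in BIK (-0.15 at a lower clustering resolution). Dividing lineage-like cells held 74 and 119 of 9938 genes at least 2-fold higher and lower in BL and 84 and 251 of 10047 in BIK, with early auxin genes at -0.51 and -1.53 and heat shock genes at -1.47 in BIK. Guard mother cell-like cells held 40 and 135 of 9157 genes in BL and 75 and 280 of 9286 in BIK, mesophyll-like cells 98 and 363 of 6615 and 75 and 184 of 6657, and young guard cell-like cells 85 and 115 of 9309 and 75 and 184 of 9560. Simulated counting noise reached 8 and 9 genes in the young guard cell-like class and at most 5 in the others.

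In the fusion library UMIs of mitochondrial genes were 0.0200% of the total and those of plastid genes 0.530%. The DMSO, BL and BIK libraries held 0.207%, 0.352% and 0.271% and 1.95%, 1.22% and 1.87%. Transposable element loci took 0.0378% of UMIs in the fusion library (0.0373% to 0.0383%).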
